A study of Mus musculus with 4 samples.

How the data were processed

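RNA was measured in 4 libraries, 2 of CCR7hiCD137lo and 2 of CCR7loCD137hi cells, sorted from Th1 cultures of mouse splenic CD4 T cells. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA. The FPKM values, fragment counts divided by transcript length and library depth, were made by the authors and deposited as 1 gene table per library, and per the file headers these have the columns of a Cufflinks gene-level table. Per the submitters' processing notes, Bowtie 0.12.8, TopHat 1.3.2, Cufflinks 2.0.2 and build mm10 were used, with no role or order given. The annotation, the filters, any scaling between libraries and whether the strand was used are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Reads were not analysed here.

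Each table held 23746 entries for 23284 gene symbols. For 240 symbols with several entries the entry with the highest mean FPKM was used, which left out 462 entries. Of the symbols, 25 had been turned into dates and were kept as they stood, and 7788 were at 0 in every library. Short RNA genes (805 entries, symbols starting with Mir, Snor or Rnu) held 18.2% and 17.2% of summed FPKM in CCR7hiCD137lo replicates 1 and 2 and 14.9% and 17.3% in CCR7loCD137hi replicates 1 and 2, although a gene shorter than a fragment is measured poorly by such libraries. Printed coordinates are those of the files with the start raised by 1, since 11596 starts were 1 below the RefSeq start and 698 equalled it. Gene annotation came from GENCODE and RefSeq on mm10.

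Depth is not stated, and was estimated from low values. Among genes under 0.3 FPKM, 78.8%, 77.2% and 77.6% of ratios to CCR7hiCD137lo replicate 1 (CCR7loCD137hi replicate 1, CCR7hiCD137lo replicate 2 and CCR7loCD137hi replicate 2) lay within 0.002 in natural log of a ratio of whole reads, where chance gives 4.5%, 4.5% and 4.1%. The relative depths were 0.564, 0.631 and 0.306 of that library. Absolute depth was set from single-exon genes with an assumed fragment length of 200 nt, and so is approximate. A gene of 1 kb with 3 fragments would stand at 0.145, 0.23, 0.258 and 0.474 FPKM in CCR7hiCD137lo replicates 1 and 2 and CCR7loCD137hi replicates 1 and 2, and these floors cover counting error only.

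Groups and replicate numbers came from the labels. Within CCR7hiCD137lo and CCR7loCD137hi, Pearson's r across 10496 genes, which are not independent replicates, was 0.950 and 0.923, and between the groups it ran from 0.909 to 0.935, so the libraries did not all lie closest to the other of their group. The median absolute log2 difference was 0.190 and 0.239 within the groups, and between them 0.177 for the libraries numbered 1, 0.185 for those numbered 2, and 0.228 and 0.287 across numbers, with no value above 0 shared by any 2 libraries. Genes with a mean FPKM of at least 1 were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (a linear model with moderated variances and a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 2.54. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so limma's test, which borrows spread across genes, was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.

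Gene lists fixed before the data were examined, 28 in all, were tested with camera of limma at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 25 lists with at least 5 tested members. They covered de novo fatty acid synthesis, cholesterol synthesis, lipid uptake and storage, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle, the respiratory chain, amino acid transport and ATF4 targets, hypoxia, naive and central memory genes, Th1 effector genes, Treg genes, Th2, Th17 and Tfh genes, activation and NF-kB targets, inhibitory receptors, anti-apoptotic and pro-apoptotic genes, S phase, G2 and M phase, interferon-stimulated genes, migration and adhesion receptors, translation and ribosome biogenesis, cytosolic ribosomal proteins, pan T cell genes, and markers of CD8 T and NK cells, B cells, myeloid and dendritic cells, and erythroid cells and platelets. Some genes stand in more than 1 list. Camera with an estimated correlation takes its degrees of freedom from the residuals, here 2, so few lists could pass it. Its correlation comes from the spread within groups, which includes any difference between replicate numbers. The genes to be named were set by a rule: Ccr7, Tnfrsf9, Acaca and Fasn, up to 12 called genes in each direction with a mean of at least 5 FPKM in the higher group, and in each list up to 4 called members or, with fewer than 2, the 2 most expressed. Others are said to have been chosen after their values were seen, and the results of some genes are not reported here.

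The test was run on 20 simulated data sets of 10374 genes for the comparison of CCR7loCD137hi with CCR7hiCD137lo. Each had 200 changed genes, drawn from the more expressed ones, and a further list of 30 genes shifted 2-fold. Of the 200, the test called 16.1% of genes changed 2-fold, 81.9% of those changed 4-fold and 96.9% of those changed 16-fold. Unchanged genes made up 5.9% of calls. The simulated spread was independent between genes, with no difference between replicate numbers. A simulated set had a median of 143 calls, against 6 in the real data. With more calls, an adjusted p under 0.05 is reached at a larger unadjusted p. The percentages therefore do not give the share of such changes found in the real data. In the real data a gene that was not called can still have a large fitted change. Tnfrsf9, with a log2 fold change of 5.51, had a limma adjusted p of 0.214. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter or a minimum mean of 5 FPKM, rescaling by median ratios, quantile normalization, no trend, a robust fit, the replicate number as a block, leaving out each library, other thresholds, and camera on ranks. Leaving out short RNA genes, alone or with the block, was added after seeing the data. Leaving out 1 library makes the replicate numbers unequal between the groups, so any difference between replicate numbers enters those fits.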

Results

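Polyadenylated RNA was profiled in 4 libraries of mouse CD4 T cells, the helper lineage of T cells. Splenic CD4 T cells of BALB/c mice, an inbred strain, had been stimulated in Th1 culture, which drives them toward interferon-gamma production, with 15 ng/ml interleukin-2 and 10 ng/ml interleukin-12. The labels give the length of culture as 4 days in one field and 5 days in another. Cells were then sorted by flow cytometry into a CCR7hiCD137lo and a CCR7loCD137hi population, with 2 libraries of each. CCR7 is a chemokine receptor that guides T cells to lymph nodes, and CD137 is a costimulatory receptor of activated T cells. The libraries are numbered 1 and 2 within each population, and nothing in the labels says whether they came from separate mice or cultures. The p-values below therefore measure only the spread between these samples, which may be technical. Estimated depth was 20600000 and 13000000 fragments for CCR7hiCD137lo replicates 1 and 2, and 11700000 and 6300000 for CCR7loCD137hi replicates 1 and 2. One fragment on a transcript of 1 kb was worth 0.0484, 0.0768, 0.0858 and 0.158 FPKM in these libraries, in the same order. Expression levels are FPKM, given as mean ± SD (n = 2), and fold changes are on the log2(FPKM + 1) scale, positive where CCR7loCD137hi was higher.

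The comparison addressed how the sorted populations differ in expression, in a study concerned with acetyl-CoA carboxylase 1, fatty acid synthesis and the capacity of CD4 T cells to form memory. The genes used for sorting followed the labels in every library. Ccr7 (mm10 chromosome 11, 99144199 to 99155077) stood at 93.4 and 118.4 FPKM in CCR7hiCD137lo and at 39.6 and 38.2 FPKM in CCR7loCD137hi. Tnfrsf9 (chromosome 4, 150920155 to 150946102), which encodes CD137, stood at 0.961 and 6.25 FPKM in CCR7hiCD137lo and at 158.2 and 183.8 FPKM in CCR7loCD137hi. Their log2 fold changes were −1.41 (SE 0.159) and 5.51 (SE 0.641), and neither passed limma's test over all genes (adjusted p = 0.213 and 0.214). Without CCR7hiCD137lo replicate 1 or replicate 2, which leaves 1 library in that group, the log2 fold change of Tnfrsf9 was 4.57 and 6.45. Both genes check the labels and are no finding.

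Ifitm1, Ly6c1 and Ly6c2, all protein-coding genes for small membrane or membrane-anchored proteins, were higher in CCR7loCD137hi. Ifitm1, a member of the interferon-induced transmembrane family (chromosome 7, 140967429 to 140969827, plus strand), was at 1.32 ± 0.479 FPKM in CCR7hiCD137lo and at 104.8 ± 31.0 FPKM in CCR7loCD137hi, a log2 fold change of 5.5 (SE 0.275, limma adjusted p = 0.0367). Ly6c2 (chromosome 15, 75108161 to 75111949, minus strand), which encodes a Ly6C surface antigen of T cells and monocytes, was at 13.0 ± 0.477 against 71.7 ± 2.37 FPKM (2.38, SE 0.12, limma adjusted p = 0.0367). Its near-identical neighbour Ly6c1 (chromosome 15, 75044018 to 75048837, minus strand) was at 12.2 ± 0.137 against 70.7 ± 7.0 FPKM (2.44, SE 0.134, limma adjusted p = 0.0425). Ly6c1 and Ly6c2 share so much sequence that reads of one can be counted on the other, so which of them differed is uncertain. Each difference was seen in 2 of 2 libraries against 2 of 2.

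The other called genes were 3 microRNA genes, each listed at 0 in both libraries of one population. Mir343 (chromosome 7, 19386643 to 19386717, plus strand) lies inside Ercc2 and overlaps 11 nt of its coding exon, with an antisense gene, Gm26852, on the other strand. It was listed at 0 in both CCR7hiCD137lo libraries and at 954.8 and 757.1 FPKM in CCR7loCD137hi (limma adjusted p = 0.000945). Mir678 (chromosome 10, 76207326 to 76207409, minus strand) lies within an untranslated part of a Prmt2 exon and was listed at 0 in both CCR7hiCD137lo libraries and at 586.5 and 337.3 FPKM in CCR7loCD137hi (limma adjusted p = 0.0108). Mir3096b (chromosome 5, 23852201 to 23852291) overlaps Snord93 within an intron of a long noncoding RNA gene and had the opposite pattern, at 113.6 and 270.2 FPKM in CCR7hiCD137lo and 0 in both CCR7loCD137hi libraries (limma adjusted p = 0.0449). Each spans under 100 nt, where few fragments give high FPKM, and the libraries were not made for small RNA.

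Over all 10496 genes tested, limma called 6, of which 5 were higher and 1 lower in CCR7loCD137hi. At an unadjusted p under 0.05 there were 487 genes higher and 366 lower, 8.1% of those tested. Both CCR7loCD137hi libraries lay above both CCR7hiCD137lo libraries for 16.6% of genes and below them for 21.5%. Libraries that could be swapped freely would give 16.7% each. Libraries of the same number were closer between the groups (median absolute log2 difference 0.177 and 0.185) than libraries within a group (0.19 and 0.239). So 16.7% need not be the share expected without a group difference. The calls of Ifitm1, Ly6c1 and Ly6c2 ended with no filter on low values (adjusted p = 0.188, 0.143 and 0.0980), with quantile normalization (0.0520, 0.0552 and 0.0520) and without a variance trend (0.0714 for each). Leaving out CCR7hiCD137lo replicate 1, CCR7hiCD137lo replicate 2 or CCR7loCD137hi replicate 1 ended the calls of Ly6c1 (0.108, 0.0709 and 0.0646) and Ly6c2 (0.0982, 0.0701 and 0.0876), and gave 17, 23 and 12 calls, of which 14, 12 and 11 were short RNA genes. Without CCR7loCD137hi replicate 2 there were 30 calls, 17 of them short RNA genes. The call of Mir678 ended with no filter (0.0943), and that of Mir3096b with no filter (0.272), with quantile normalization (0.0525), without a trend (0.0714) and without CCR7loCD137hi replicate 1 (0.0915) or replicate 2 (0.0526).

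**Figure D1:**
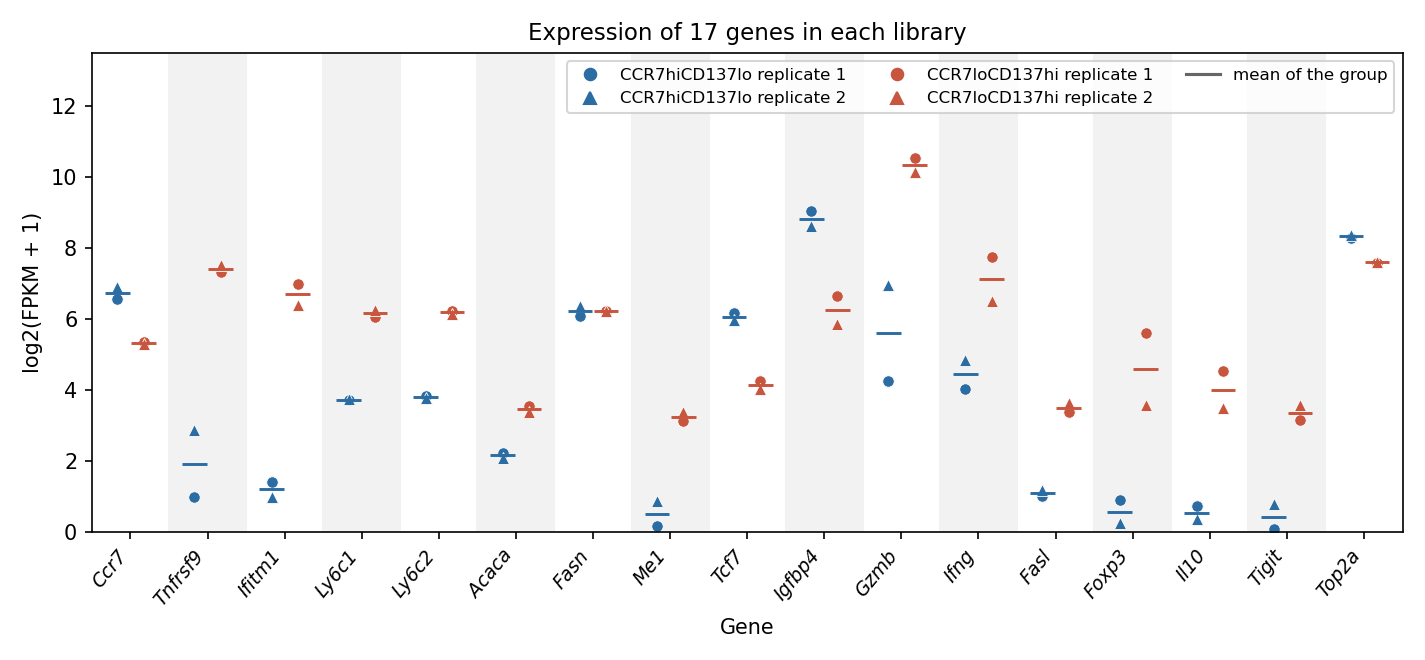
Expression of 17 genes as log2(FPKM + 1), with one symbol per library (circles for replicate 1, triangles for replicate 2; blue for CCR7hiCD137lo, red for CCR7loCD137hi) and a line at the mean of each group. Ifitm1, Ly6c1 and Ly6c2, the genes of this plot that passed the test over all genes, were at 1.32, 12.2 and 13.0 FPKM in CCR7hiCD137lo and at 104.8, 70.7 and 71.7 FPKM in CCR7loCD137hi, while Fasn was at 74.2 and 73.9 FPKM.

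Among genes of lipid metabolism, the gene for the first committed enzyme of fatty acid synthesis was higher in CCR7loCD137hi when judged within its pathway, while the gene for the synthase was level. Acaca, which encodes acetyl-CoA carboxylase 1 (chromosome 11, 84195438 to 84401651), was at 3.48 ± 0.316 FPKM in CCR7hiCD137lo and at 10.1 ± 0.870 FPKM in CCR7loCD137hi, a log2 fold change of 1.31 (SE 0.156). Fasn, the fatty acid synthase gene (chromosome 11, 120805958 to 120824547), was at 74.2 ± 9.61 and 73.9 ± 0.863 FPKM (0.001, SE 0.140, limma adjusted p = 0.999). Me1, which encodes a malic enzyme that supplies NADPH, was at 0.470 ± 0.507 against 8.51 ± 1.12 FPKM. Of 19 measured genes of de novo fatty acid synthesis, none passed limma's test over all genes (Acaca, adjusted p = 0.216; Me1, 0.213), and 2, Acaca and Me1, passed adjusted over the list alone, both higher, with 1 such call without CCR7loCD137hi replicate 1, without CCR7hiCD137lo replicate 2 or with a minimum mean of 5 FPKM. The list had 15 members fitted above 0, a median log2 fold change of 0.142, and a camera adjusted p of 0.0125 toward CCR7loCD137hi, with adjusted p = 0.518 with an estimated correlation. That camera call also ended without CCR7hiCD137lo replicate 1 (adjusted p = 0.166), without CCR7loCD137hi replicate 2 (0.164) and with no filter (0.128). Scd2 and Acly, the most expressed members, were at 286.5 ± 122.6 and 120.8 ± 36.3 FPKM in CCR7hiCD137lo and at 348.5 ± 101.8 and 132.1 ± 30.3 FPKM in CCR7loCD137hi. Me1 was chosen for naming after its values were seen.

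Other lipid lists gave no call in camera's test with the main design. Cholesterol synthesis and SREBP2 targets had 17 of 24 members fitted above 0, with 0 calls adjusted over the list alone and a camera adjusted p of 0.242. The direction turned toward CCR7hiCD137lo without CCR7hiCD137lo replicate 1 or CCR7loCD137hi replicate 2. Those fits hold the replicate numbers unequally, and 21 of 24 members were higher in replicate 2 in both groups. The turn can therefore reflect replicate number. The list had a median difference between the groups of 0.267 in replicate 1 and −0.014 in replicate 2. Its most expressed members, Fdps and Hmgcs1, were at 168.7 ± 71.3 and 121.6 ± 62.9 FPKM in CCR7hiCD137lo and at 208.6 ± 65.5 and 141.2 ± 58.7 FPKM in CCR7loCD137hi. Lipid uptake and storage had 12 of 15 members fitted above 0 and 0 calls adjusted over the list alone (camera adjusted p = 0.185, and 0.0345 without CCR7hiCD137lo replicate 2), with 1 such call without CCR7loCD137hi replicate 2. In that list Fabp5, a fatty acid binding protein gene, was at 100.3 ± 6.60 against 123.0 ± 17.3 FPKM, and Agpat3, an acyltransferase gene, at 104.7 ± 2.44 against 80.5 ± 4.59 FPKM. Fatty acid oxidation had 16 of 23 members fitted above 0, with Eci1, an enoyl-CoA isomerase gene, as the single call adjusted over the list alone (4.03 ± 0.318 against 9.10 ± 0.527 FPKM, chosen for naming after its values were seen). Its camera adjusted p was 0.0635, with 0.0417 after quantile normalization, 0.0220 without CCR7loCD137hi replicate 1 and 0.0258 without CCR7hiCD137lo replicate 2, and the Eci1 call was lost when any single library was left out, with no filter, with a minimum mean of 5 FPKM and with quantile normalization (0 calls in each). The most expressed members, Etfb and Acadl, were at 65.6 ± 1.08 and 46.7 ± 2.23 FPKM in CCR7hiCD137lo and at 91.3 ± 10.2 and 60.7 ± 7.72 FPKM in CCR7loCD137hi.

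Glycolysis, hypoxia and amino acid genes leaned toward CCR7loCD137hi as groups, with no single member passing in the main design even adjusted over the list alone. Left-out libraries gave such calls in 2 of these lists, with 1 hypoxia gene without CCR7hiCD137lo replicate 2 and 2 ATF4 targets without CCR7loCD137hi replicate 1. In glycolysis 20 of 21 genes were fitted above 0, with a median of 0.302 and a camera adjusted p of 2.78e-06, against adjusted p = 0.450 with an estimated correlation. Ldha, lactate dehydrogenase, was at 1444 ± 21.8 FPKM in CCR7hiCD137lo and 1748 ± 89.4 FPKM in CCR7loCD137hi, and Pkm2, pyruvate kinase, at 1351 ± 49.3 and 1511 ± 49.8 FPKM. All 18 measured hypoxia genes were fitted above 0, with a median of 0.632 and a camera adjusted p of 3.68e-06, against adjusted p = 0.518 with an estimated correlation. Within this list Bnip3, a mitophagy receptor gene, was at 100.2 ± 28.5 against 164.7 ± 44.3 FPKM. Egln3, a prolyl hydroxylase gene, was at 151.5 ± 107.8 against 200.3 ± 137.5 FPKM. It was at 75.3 against 103.1 FPKM in replicate 1 and 227.8 against 297.5 FPKM in replicate 2. Its fold change had the opposite sign without CCR7hiCD137lo replicate 1 or CCR7loCD137hi replicate 2, fits that hold the replicate numbers unequally. Among amino acid transport and ATF4 targets, 18 of 22 were fitted above 0 (median 0.268, camera adjusted p = 0.000127, and adjusted p = 0.40 with an estimated correlation). Atf4, a stress-response transcription factor gene, was at 116.3 ± 6.39 against 180.6 ± 12.9 FPKM, and Psat1, a serine synthesis gene, at 87.4 ± 8.37 against 100.7 ± 0.981 FPKM.

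The respiratory chain and ATP synthase list had 29 of 41 members fitted above 0 and a median of 0.065 (camera adjusted p = 0.0376, and adjusted p = 0.690 with an estimated correlation). Its camera call ended with no filter (adjusted p = 0.106), quantile normalization (0.131) or no trend (0.0673). Its direction turned without CCR7loCD137hi replicate 1 or CCR7hiCD137lo replicate 2. Those fits hold the replicate numbers unequally, and 34 of 41 members were lower in replicate 2 in both groups. Between the groups the median difference was 0.095 in replicate 1 and 0.031 in replicate 2. Cox4i1 was at 437.5 ± 3.07 against 525.4 ± 23.6 FPKM, and Atp5b at 598.7 ± 73.8 against 647.4 ± 114.4 FPKM, though with quantile normalization the sign for Atp5b turned. The tricarboxylic acid cycle had 14 of 23 members fitted above 0 (camera adjusted p = 0.498). The direction turned in the same 2 fits, and 17 of 23 members were lower in replicate 2 in both groups. Mdh2 was at 242.3 ± 39.2 against 262.3 ± 49.98 FPKM and Sdhb at 119.5 ± 6.96 against 127.5 ± 17.7 FPKM. Neither list had a call adjusted over the list alone.

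Th1 effector genes had the highest median of the 25 lists tested. Of 30 measured members, 15 were higher and 2 lower adjusted over the list alone, 26 were fitted above 0, and none passed over all genes. Gzmb, which encodes the cytotoxic protease granzyme B, was at 70.5 ± 73.9 FPKM in CCR7hiCD137lo and 1304 ± 257.9 FPKM in CCR7loCD137hi (log2 fold change 4.73, SE 0.909, limma adjusted p = 0.374). Lta, lymphotoxin alpha, was at 459.0 ± 118.9 against 521.8 ± 19.6 FPKM and did not pass. Members chosen after their values were seen were Ifng, the signature Th1 cytokine, at 21.6 ± 8.87 against 152.8 ± 87.6 FPKM, and Fasl, a death ligand, at 1.14 ± 0.190 against 10.3 ± 1.42 FPKM. Cxcr3, a chemokine receptor of Th1 cells, was among the lower members, at 52.5 ± 5.65 against 27.3 ± 2.45 FPKM, also named after its values were seen. Camera gave the list a median of 1.53 and an adjusted p of 5.60e-10, against adjusted p = 0.40 with an estimated correlation. Fits without 1 library leave 1 in its group. In them the log2 fold change of Gzmb ran from 3.38 without CCR7hiCD137lo replicate 1 to 6.07 without replicate 2. That of Ifng ran from 2.08 without CCR7loCD137hi replicate 1 to 3.32 without replicate 2.

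Genes typical of regulatory T cells, a suppressive CD4 lineage, and of other helper lineages were also higher in CCR7loCD137hi. Of 19 measured Treg genes, none passed over all genes, and 11 were higher and 1, the signalling suppressor gene Socs2, lower adjusted over the list alone (median 1.06, camera adjusted p = 2.02e-09, and adjusted p = 0.40 with an estimated correlation). With a minimum mean of 5 FPKM there were 7 such calls, 6 higher and 1 lower. The most expressed members, Il2ra and Tnfrsf18, which encode the interleukin-2 receptor alpha chain and GITR, were at 528.1 ± 13.8 and 162.7 ± 28.8 FPKM in CCR7hiCD137lo and at 447.1 ± 143.8 and 267.3 ± 4.19 FPKM in CCR7loCD137hi. Foxp3, the lineage factor of Treg cells, stood at 0.853 and 0.181 FPKM in CCR7hiCD137lo. In replicates 1 and 2 of CCR7loCD137hi it stood at 47.9 and 10.97 FPKM. Its log2 fold change was 5.05 without CCR7loCD137hi replicate 2 and 3.02 without replicate 1, fits that leave 1 library in that group. Il10, an immunosuppressive cytokine, was at 0.468 ± 0.269 against 16.2 ± 8.27 FPKM. Among 9 measured Th2, Th17 and Tfh genes, 4 were higher adjusted over the list alone (median 1.15, camera adjusted p = 7.91e-06, and adjusted p = 0.40 with an estimated correlation), with 2 without CCR7hiCD137lo replicate 1 or without CCR7loCD137hi replicate 1 and 1 with a minimum mean of 5 FPKM. Il13 and Gata3, a cytokine and the lineage factor of Th2 cells, were at 0.101 ± 0.0740 and 6.20 ± 0.340 FPKM in CCR7hiCD137lo and at 7.32 ± 2.11 and 11.7 ± 1.60 FPKM in CCR7loCD137hi. The most expressed members, Sh2d1a and Ccr4, were at 78.3 ± 24.4 against 67.7 ± 16.2 FPKM and 16.5 ± 5.28 against 21.9 ± 3.29 FPKM. Socs2, Foxp3, Il10, Il13 and Gata3 were named after their values were seen.

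Markers of CD8 T and NK cells, which a selection of CD4 T cells should remove, were higher in CCR7loCD137hi together with these effector and Treg genes. Of 7 measured, 5 were higher adjusted over the list alone (median 1.45, camera adjusted p = 4.48e-07, and adjusted p = 0.40 with an estimated correlation), with 2 without CCR7hiCD137lo replicate 1 or with a minimum mean of 5 FPKM and 1 without CCR7loCD137hi replicate 1. Eomes, a T-box factor, was at 13.3 ± 5.48 against 27.5 ± 1.47 FPKM, and Klrk1, which encodes the receptor NKG2D, at 6.83 ± 3.60 against 16.0 ± 0.700 FPKM. CCR7loCD137hi replicate 1 stood apart for markers under the minimum for testing, chosen after their values were seen. Cd8a, part of the CD8 receptor, was at 3.68 FPKM there and at 0.218 FPKM in replicate 2, against 0 and 0.026 FPKM in CCR7hiCD137lo. Ncr1, an NK cell receptor, was at 1.91 and 0.251 FPKM, and listed at 0 in both CCR7hiCD137lo libraries. The single tested B cell marker, Cd74, which other antigen-presenting cells also express, was at 23.3 and 5.15 FPKM in CCR7loCD137hi. In CCR7hiCD137lo it was at 0.920 and 1.13 FPKM. Its log2 fold change ran from 1.61 to 3.59 as each library was left out, which leaves 1 in a group. Of myeloid and dendritic cell markers 3 could be tested, too few for a list test. Among them Cst3 was at 45.0 ± 0.636 against 63.0 ± 0.607 FPKM and Ctss at 42.8 ± 4.43 against 34.8 ± 0.705 FPKM. No erythroid or platelet marker reached the minimum.

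Activation genes were higher in CCR7loCD137hi. Of 36 measured T cell activation and NF-kB targets, 10 were higher and 1 lower adjusted over the list alone (median 0.609, camera adjusted p = 1.05e-10, and adjusted p = 0.40 with an estimated correlation), with 4 calls without CCR7loCD137hi replicate 1 and 7 without CCR7hiCD137lo replicate 1 or with no filter. Junb, an AP-1 subunit gene, was at 82.1 ± 19.5 against 147.0 ± 2.79 FPKM, and Myc at 101.6 ± 28.4 against 137.1 ± 29.1 FPKM, which did not pass. Nr4a1, induced by T cell receptor signalling, was at 7.87 ± 1.35 against 30.1 ± 0.705 FPKM, and Tnfsf8, the CD30 ligand gene, was the lower member at 31.6 ± 3.56 against 11.6 ± 1.05 FPKM. Both were named after their values were seen. Inhibitory receptors were split, with 7 of 14 higher and 2 lower adjusted over the list alone (median 0.664, camera adjusted p = 0.000875, and adjusted p = 0.450 with an estimated correlation). Without CCR7hiCD137lo replicate 1 the list had 4 calls, and with a minimum mean of 5 FPKM its camera call ended (adjusted p = 0.194). Ctla4 was at 30.5 ± 9.89 against 104.4 ± 48.6 FPKM and Cd5 at 91.9 ± 1.93 against 86.0 ± 3.48 FPKM, which did not pass. The lower members, named after their values were seen, were Btla (49.9 ± 2.10 against 14.0 ± 5.01 FPKM) and Cd200 (27.0 ± 6.25 against 8.95 ± 2.77 FPKM).

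Migration and adhesion receptors had 5 higher and 1 lower member among 22 adjusted over the list alone (median 0.33, camera adjusted p = 0.000454, and adjusted p = 0.40 with an estimated correlation). Leaving out CCR7hiCD137lo replicate 1 or CCR7loCD137hi replicate 2 left 1 call, and leaving out CCR7hiCD137lo replicate 2 left 3, all of them higher. With a minimum mean of 5 FPKM there was 1 call, a lower one. Selplg, a selectin ligand gene, did not pass, at 153.9 ± 2.89 against 160.7 ± 17.1 FPKM, and its sign turned with quantile normalization. Ccr2, a chemokine receptor of effector cells named after its values were seen, was at 0.812 ± 0.260 against 7.65 ± 1.33 FPKM.

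Naive and central memory genes went both ways. Of 29 measured members, Ly6c1 and Ly6c2 were higher over all genes, while 6 were lower in CCR7loCD137hi adjusted over the list alone, and the list as a whole had a median of −0.088 and no camera call (adjusted p = 0.238, and 0.0372 without CCR7loCD137hi replicate 2). The lower members, named after their values were seen, were Tcf7, Igfbp4, Dapl1, Actn1, Foxp1 and Il6ra. Tcf7, a transcription factor of naive and memory T cells, was at 66.4 ± 6.71 against 16.8 ± 1.97 FPKM (log2 fold change −1.93, SE 0.153, limma adjusted p = 0.0876). Igfbp4, a secreted growth factor binding protein, was at 459.5 ± 93.9 against 78.7 ± 30.4 FPKM (−2.57, SE 0.317, limma adjusted p = 0.218). Ly6c1 and Ly6c2 also mark effector T cells.

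Proliferation genes were lower in CCR7loCD137hi as groups, by small amounts. In the G2 and M phase list 34 of 35 members were fitted below 0 (median −0.262, camera adjusted p = 2.02e-09, and adjusted p = 0.40 with an estimated correlation), and in the S phase list 31 of 35 (median −0.194, camera adjusted p = 1.44e-05, and adjusted p = 0.450 with an estimated correlation). Both lists had 0 calls adjusted over the list alone, and the G2 and M phase list had 1, lower, with quantile normalization or without short RNA genes, a setting chosen after the results were seen. Top2a, a topoisomerase of dividing cells, was at 320.1 ± 10.0 against 192.7 ± 3.08 FPKM, and Birc5, a mitotic regulator, at 219.9 ± 9.93 against 190.3 ± 25.1 FPKM. Pcna and Rrm2, which act in DNA replication, were at 405.4 ± 13.9 and 185.2 ± 6.25 FPKM in CCR7hiCD137lo and at 367.7 ± 44.5 and 156.5 ± 22.5 FPKM in CCR7loCD137hi. Interferon-stimulated genes were lower as well, with 16 of 19 fitted below 0 and 0 calls adjusted over the list alone, or 2, both higher, with no filter (median −0.385, camera adjusted p = 8.44e-05, and adjusted p = 0.40 with an estimated correlation). Igtp and Gbp2, which encode interferon-induced GTPases, were at 369.1 ± 26.0 and 123.9 ± 23.9 FPKM in CCR7hiCD137lo and at 302.1 ± 23.2 and 70.7 ± 33.9 FPKM in CCR7loCD137hi.

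Pro-apoptotic genes had 12 of 18 members fitted above 0 and Fasl as the single call adjusted over the list alone (median 0.177, camera adjusted p = 0.00989, and adjusted p = 0.450 with an estimated correlation), and the camera call ended without CCR7loCD137hi replicate 1 (adjusted p = 0.114) and with a minimum mean of 5 FPKM (0.112). Bax was at 143.7 ± 1.01 against 166.1 ± 31.3 FPKM and Casp8 at 68.4 ± 2.56 against 57.0 ± 4.29 FPKM. Anti-apoptotic genes had 13 of 16 members fitted above 0, no call adjusted over the list alone and a camera adjusted p of 0.0817, with 0.0345 without CCR7hiCD137lo replicate 2 and 0.0375 without CCR7loCD137hi replicate 2. Its most expressed members were the kinase genes Pim2 and Pim1, at 319.4 ± 66.2 and 250.3 ± 30.1 FPKM in CCR7hiCD137lo and at 341.9 ± 60.3 and 268.2 ± 34.6 FPKM in CCR7loCD137hi.

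Genes of cytosolic ribosomal proteins were slightly higher in CCR7loCD137hi as a group, with 37 of 40 fitted above 0 and 0 calls adjusted over the list alone (median 0.163, camera adjusted p = 1.32e-07, and adjusted p = 0.450 with an estimated correlation), a call that ended with quantile normalization (0.131). Rpl41 was at 3606 ± 239.1 against 4354 ± 75.2 FPKM and Rplp1 at 2481 ± 5.42 against 2700 ± 81.0 FPKM. Translation and ribosome biogenesis genes had a median of −0.013, a mean of 0.022 and a camera direction toward CCR7loCD137hi (adjusted p = 0.535), so that these measures differed in sign. The list leaned toward CCR7loCD137hi without CCR7hiCD137lo replicate 1 or CCR7loCD137hi replicate 2. It leaned toward CCR7hiCD137lo without CCR7loCD137hi replicate 1 or CCR7hiCD137lo replicate 2. These fits hold the replicate numbers unequally in the 2 groups, so they do not measure the groups alone. In the list, the median of replicate 2 minus replicate 1 was −0.405 in CCR7hiCD137lo and −0.612 in CCR7loCD137hi. Between the groups the median difference was 0.123 in replicate 1 and −0.147 in replicate 2. Npm1 and Eif5a were at 510.1 ± 130.0 and 689.7 ± 83.8 FPKM in CCR7hiCD137lo and at 642.2 ± 174.8 and 749.5 ± 173.7 FPKM in CCR7loCD137hi, with the sign for Eif5a turned by quantile normalization. Pan T cell genes had 13 of 19 members fitted below 0 (median −0.055, camera adjusted p = 0.535), with Thy1 at 470.2 ± 21.2 against 538.4 ± 28.3 FPKM and Cd2 at 306.5 ± 21.3 against 369.2 ± 25.9 FPKM. Neither of these last lists had a call adjusted over the list alone.

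Over the 25 lists with enough tested members, camera with its preset correlation called 17, of which 14 were higher and 3 lower in CCR7loCD137hi. With an estimated correlation 0 lists were called, with ATF4 targets and interferon-stimulated genes at an unadjusted p of 0.0478 and 0.0464, and fry, which asks whether the genes of a list move on balance one way, also called 0 of the 25 lists, 3 of them at an unadjusted p under 0.05, with a smallest adjusted p of 0.0757 for interferon-stimulated genes. Fry's other test, of change in either direction, passed for 11 of the 25 lists. Among them were fatty acid oxidation, with the smallest adjusted p in this test (6.73e-05), naive and central memory genes (0.00482) and fatty acid synthesis (0.0174). Neither of fry's tests compares a list with other genes. Camera with an estimated correlation had only 2 residual degrees of freedom, so its 0 calls do not show that the lists did not differ.

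**Figure D2:**
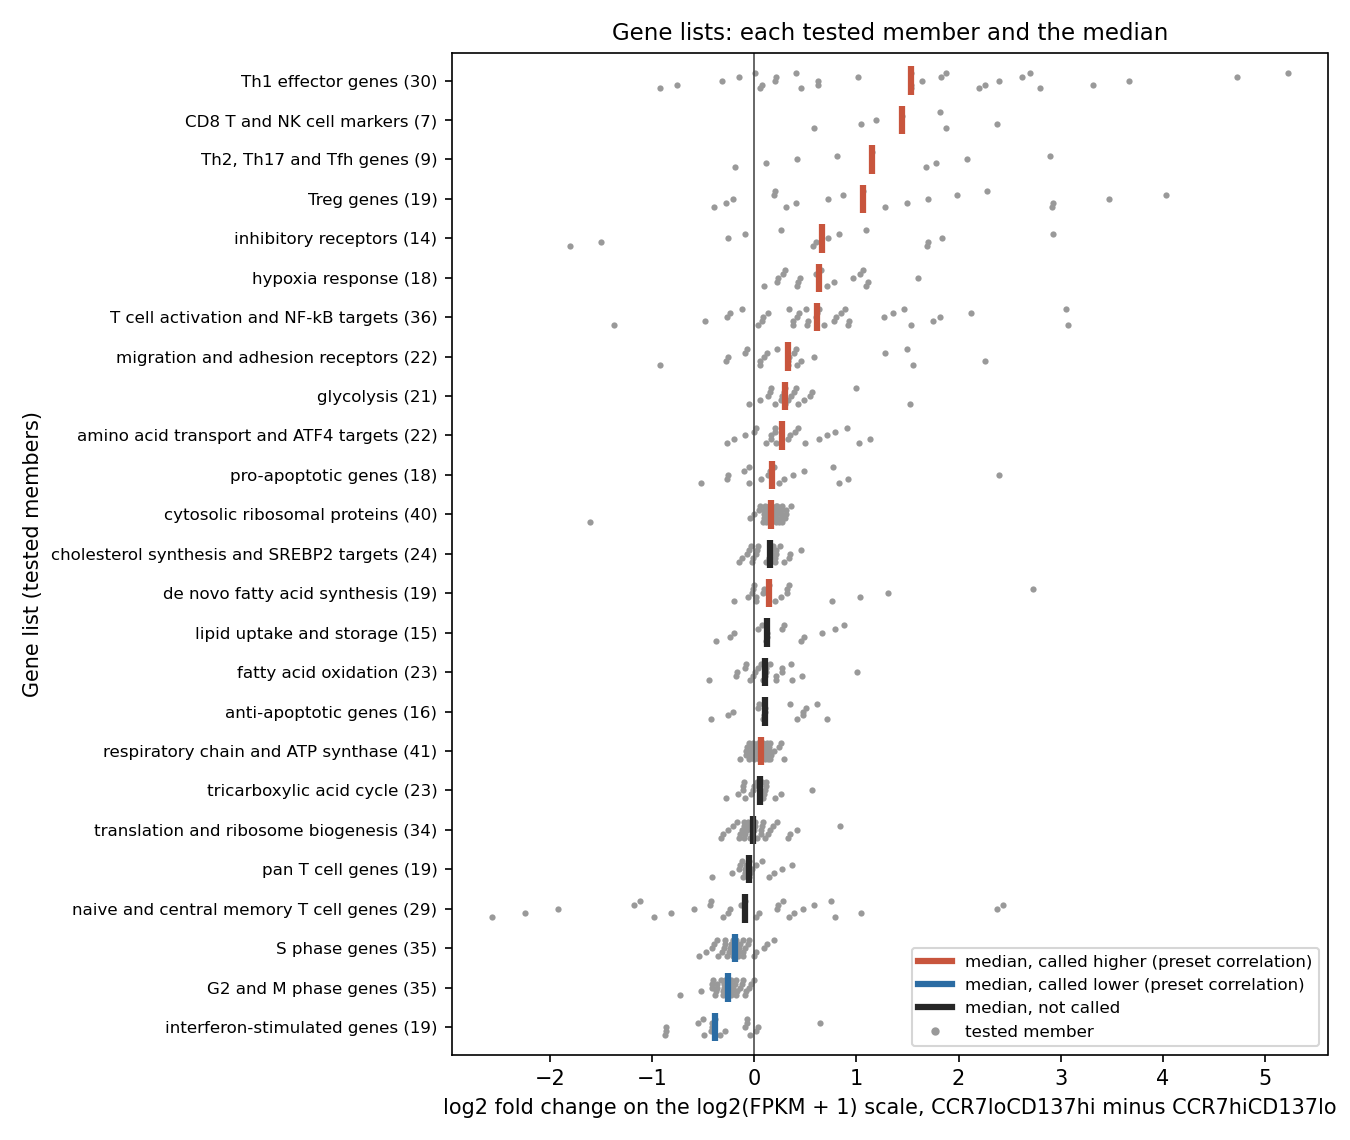
Log2 fold change of every tested member (grey points) and the median (coloured bar) of 25 gene lists, on the log2(FPKM + 1) scale, CCR7loCD137hi minus CCR7hiCD137lo, with the number of tested members beside each name. Red and blue bars mark lists that camera called higher or lower with its preset correlation, and the medians run from −0.385 for interferon-stimulated genes to 1.53 for Th1 effector genes.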

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

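The settings without short RNA genes were chosen only after the results were seen, and all other settings before. Of comparisons of named genes with an alternative, 1439 kept direction and side of the threshold, 91 newly passed, 21 no longer passed and 34 turned direction. For list tests these numbers were 380, 16, 44 and 8. Gene calls numbered 6 as reported, 8 and 7 with pseudocounts of 0.1 and 0.5, and 6 with median rescaling, a robust fit or a minimum mean of 5 FPKM. They numbered 1 with no filter, 2 with quantile normalization, 2 without a trend, 14 at an adjusted p under 0.10 and 3 without short RNA genes. Scaling moved the median log2 fold change of all genes from −0.012 to between −0.043 and 0.002. Camera called 0 lists with an estimated correlation and fry's test of movement one way called 0, against 13 to 21 in the other settings. With quantile normalization the log2 fold changes of Fasn, Atp5b, Selplg and Eif5a were −0.001, −0.032, −0.007 and −0.046. Where not shown by the setting itself, the cause was not tested. Depth limits the low values, since 1 fragment on 1 kb was worth 0.158 FPKM in CCR7loCD137hi replicate 2.

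Leaving out a library leaves 1 in its group, assumed to vary like the other group, with 1 residual degree of freedom. The replicate numbers are then unequal between the groups, so a turn of direction can reflect a difference between replicate numbers. Gene calls then numbered 12 to 30, and Tnfrsf9 had a log2 fold change of 4.57 to 6.45. Adjusted p in camera ran from 3.16e-05 to 0.415 for cholesterol synthesis, 0.0428 to 0.537 for the tricarboxylic acid cycle, 6.49e-05 to 0.592 for the respiratory chain and 2.90e-07 to 0.0125 for translation, each with its direction turned in some. The log2 fold change of Fasn ran from −0.13 to 0.13, Scd2 −0.13 to 0.77, Acly −0.17 to 0.45, Fdps −0.11 to 0.78, Hmgcs1 −0.30 to 0.80, Mdh2 −0.084 to 0.30, Sdhb −0.053 to 0.23, Atp5b −0.074 to 0.29, Egln3 −0.38 to 1.21, Lta −0.058 to 0.48 and Il2ra −0.61 to 0.056. Those of Sh2d1a ran from −0.51 to 0.12, Pim2 −0.11 to 0.32, Pim1 −0.033 to 0.23, Selplg −0.05 to 0.17, Eif5a −0.13 to 0.34, Cd4 −0.65 to 0.22, Cd3e −0.20 to 0.10 and Rps27 −4.21 to 0.99. With no turn of direction, Gzma ran from 4.12 to 6.32, Gzmb 3.38 to 6.07, Gzmc 1.84 to 3.40, Prf1 2.48 to 4.16, Foxp3 3.02 to 5.05, Il1rl1 1.62 to 2.93, Cd74 1.61 to 3.59, Lgals3 2.46 to 3.65, Mt1 2.35 to 4.14 and Mt2 2.62 to 4.11.

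The labels do not say that a replicate number marks one culture. Across genes, replicate 1 minus replicate 2 in one group correlated with the same difference in the other at 0.214, and at 0.6 without short RNA genes, a hint from the data, not the design. With a replicate block, limma called 42 genes (36 higher and 6 lower in CCR7loCD137hi), among them the 6 reported. With short RNA genes also left out it called 545 (418 higher and 127 lower). With the block alone camera called 19 lists, adding cholesterol synthesis (adjusted p = 0.0255) and lipid uptake (0.0312). Calls adjusted over the list alone then numbered 14 in glycolysis, 15 in hypoxia, 6 in ATF4 targets and 4 in fatty acid synthesis. They numbered 23 in activation genes (21 higher), 13 in naive and central memory genes (5 higher), 7 in interferon-stimulated genes (6 lower) and 1, lower, in G2 and M phase. With short RNA genes also left out, G2 and M phase had 18, all lower, and interferon-stimulated genes 11 (10 lower). Ribosomal protein genes had 15, all higher. With the block and without short RNA genes Ccr7 and Tnfrsf9 passed, at log2 fold changes of −1.41 and 5.51, as did Acaca and Me1 (adjusted p = 0.010 and 0.0059), of which Me1 also passed with the block alone (0.0445).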

Other observations

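The tests of explanations in this part were chosen only after the results were seen, as were the genes named and the comparison of replicate numbers. S100a4, Lgals3, Mt1 and Mt2, which are in none of the fixed lists, were higher in both CCR7loCD137hi libraries without passing limma's test over all genes. S100a4 encodes an S100 calcium-binding protein. It was at 1.67 ± 0.962 FPKM in CCR7hiCD137lo and 33.2 ± 0.866 FPKM in CCR7loCD137hi (SD, n = 2, limma adjusted p = 0.0876). Its log2 fold change ran from 3.35 to 4.11 as each library was left out. Lgals3, which encodes galectin 3, was at 9.90 ± 6.03 against 82.6 ± 0.481 FPKM, and the metallothionein genes Mt1 and Mt2 at 11.1 ± 9.40 against 94.8 ± 4.39 FPKM and 1.16 ± 1.45 against 18.6 ± 1.57 FPKM. For these 3 genes, in the same order, the log2 fold change ran from 2.46 to 3.65, 2.35 to 4.14 and 2.62 to 4.11. Each such fit leaves 1 library in a group. Ms4a4c, a gene for a four-pass membrane protein family, was lower, at 84.4 ± 6.79 against 27.9 ± 0.0820 FPKM (limma adjusted p = 0.0876). The neighbours of Ifitm1 in its family, Ifitm2 and Ifitm3, were at 52.8 ± 14.6 against 129.1 ± 32.5 FPKM and 56.4 ± 19.8 against 150.1 ± 54.4 FPKM.

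Some metabolic groups differed between libraries numbered 2 and libraries numbered 1 in both populations. All 18 hypoxia genes were higher in replicate 2 in both (camera adjusted p = 8.92e-09), as were 21 of 24 genes of cholesterol synthesis (2.72e-08). By contrast, 32 of 34 genes of translation and ribosome biogenesis (9.06e-16) and 34 of 41 of the respiratory chain (3.65e-07) were lower in both. De novo fatty acid synthesis (13 of 19, 0.0329) and glycolysis (15 of 21, 0.00385) were also higher, and the tricarboxylic acid cycle (17 of 23, 0.00205) and S phase genes (17 of 35, 0.00178) lower. With an estimated correlation each of these lists had a camera adjusted p of 0.875. With replicate number in the model that test had 1 residual degree of freedom, so it could hardly pass and decides nothing here.

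Of the 6 called genes, 3 are microRNA genes listed at 0 in both libraries of one group. For Mir343 and Mir3096b, a level difference of the surrounding Ercc2 and 2700038G22Rik is argued against. These genes differed by at most 0.054 on the log2 scale in the direction of the call (Ercc2, −0.005, SE 0.123, and 2700038G22Rik, −0.054, SE 0.401), by a limit of 1 set once the values had been seen. Snord93, which overlaps 71 nt of Mir3096b, and Gm26852, antisense at Mir343, were not compared, so reads from them are not excluded. Few reads on genes shorter than a fragment, coming and going whatever the group, may account for these calls: of 20 short RNA genes above 0 in exactly 2 libraries, 5 were split by group, 7 by replicate number and 8 crosswise, and with values under 0.001 FPKM taken as 0, of 20 such genes 6, 7 and 7. For Mir678 the surrounding Prmt2 differed by 0.651 (SE 0.238), and a difference in that transcript cannot be told apart from the other explanations, since the limit of 1 lies within 2 SE. A difference between the sorted populations stays open and untested.

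Treg genes were higher in CCR7loCD137hi by camera with its preset correlation (adjusted p = 2.02e-09), with adjusted p = 0.40 with an estimated correlation, 0.184 in fry and 0 of 19 called over all genes. Treg cells, which are CD4 T cells that a CD4 selection would keep, could be the source if their share was larger in replicate 1, where the excess of Foxp3 over the CCR7hiCD137lo mean was 4.53 times that in replicate 2. The other 11 Treg genes with separate libraries had a median factor of 1.34, from 0.26 for Capg to 3.18 for Il1rl1, lower than that of Foxp3. This does not exclude the explanation, since it assumes 1 Treg profile in both libraries and the most abundant of these genes, Tnfrsf18, Tnfrsf4 and Capg, stood at 74.1 FPKM or more in both CCR7hiCD137lo libraries as well, so the explanation cannot be told apart from a difference between the sorted populations.

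Gzma, Gzmb, Gzmc, Prf1 and Nkg7 are cytotoxic genes picked from the Th1 effector list after their values were seen. They were higher in CCR7loCD137hi by limma adjusted over that list alone. Over all genes they did not pass (limma adjusted p from 0.285 for Gzma to 0.462 for Nkg7). CD8 T or NK cells, which a selection of CD4 T cells should remove, are a candidate source, and the excess in replicate 1 over that in replicate 2 had a factor of 1.35 for Gzmb, the most abundant, and up to 4.83 for Gzma over these 5 genes, against 17.9 for Cd8a and 7.6 for Ncr1. All 5 genes thus lay more than 1.5 times below both markers. Klra3, Klra7 and Klrb1c, other genes of the CD8 and NK marker list, had factors of 1.87, 2.31 and 2.99, within the range of the 5 genes. The factors of these marker genes ran from 1.87 to 17.9, so they gave no single value to compare. The factors therefore decide nothing about these cells as the one source. Cd8a and Ncr1 stood at 0.218 and 0.251 FPKM in replicate 2, under the 0.474 FPKM of 3 fragments on 1 kb. Klra3 and Klra7 stood above this floor there, at 1.06 and 0.786 FPKM, but Klrb1c stood under it, at 0.13 FPKM. The condition that Cd8a and Ncr1 exceed the floor was added after the factors had been seen. With that condition, and with the factors of these other marker genes, the explanation cannot be told apart from a difference between the sorted populations, which was not tested.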
